A study of Saccharomyces cerevisiae with 14 samples.

How the data were processed

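Chromatin immunoprecipitation (ChIP) DNA was hybridised against input DNA on 14 arrays of budding yeast open reading frames and intergenic regions. Per the labels, the ChIP channel was Cy5 and the input channel Cy3 on each array, with no exchange of dyes. The values as deposited are log ratios of ChIP over input, 1 column per sample, and were taken as log2. The submitters' notes name the ratio of medians of the Cy5 over the Cy3 wavelength as the starting quantity. The base of the logarithm is not stated. Base 10 was excluded because the values would then exceed what a scanner can record, and base 2 was assumed for every value printed as log2 or as a fold. Base e was not excluded, and with it each log2 value and fold would be larger. The deposited columns were already centred, with array medians no farther than 0.00136 from 0. Background correction, within-array normalization, averaging of spots and genome build are not given in the sources used here. Signal over background of single spots was not analysed here, and the number of arrays limits the precision.

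Groups, replicate numbers and times were taken from the labels. The description field of the pADH1-Spo11 and Gal4BD-alone arrays names binding sites, against their titles, protocol and time, which were followed. Binding arrays were made at 0 h from crosslinked cells, and DSB arrays at 6 h without crosslinking. The series design states that replicates came from independent cultures. Deviations of arrays from their group means were compared between groups. Arrays with the same replicate number had a median correlation of 0.00495 and arrays with different numbers 0.00318, so replicate numbers were not treated as pairs. No array repeated another.

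Of 13009 features, 859 had no value on any array. Each array was centred on its median and no loess, quantile or scale normalization was applied. The fit for breaks used the 11 DSB arrays of 4 strains in limma 3.58.1 under R 4.3.3 (lmFit and eBayes), with features that had values on at least 2 arrays of every strain, which left 11298. The binding arrays were fitted alone, over 12092 features, because crosslinking, antibody and time differed. P-values were adjusted by the Benjamini-Hochberg method over features, and a contrast was called at an adjusted p under 0.05. A feature was called enriched in a strain at an adjusted p under 0.05 for a group mean above 0 together with a mean log2 of at least 1. Called neighbours with at most 1 feature position between them were counted as 1 run. Bound features were compared with broken features by Fisher's exact test, two-sided, with exact Clopper-Pearson 95% intervals. Neighbouring features share DNA fragments and are not independent, which these tests and intervals do not allow for.

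Feature lists were fixed before the data were examined. They were Gal4 target genes, known DSB hotspots, early meiotic genes, glycolytic genes, loci used in constructs and as markers, ribosomal protein genes, seripauperin and COS genes, transfer RNA genes, Ty elements with long terminal repeats, chromosome ends, centromere sides, the 3 shortest chromosomes I, III and VI, intergenic features, and the features bound by Gal4BD-Spo11. The list of bound features was chosen on samples of this series. A member was a feature in the gene or in the intergenic region directly upstream. Lists were tested with limma's camera on features with values on all arrays, at a preset correlation of 0.01, with adjustment over the 14 lists of each contrast, and again with an estimated correlation. Counts adjusted over the list alone used the p-values of its members only. Names and gene order came from the RefSeq annotation of the current reference genome. Since the array's build was not known, no coordinates were used. Chromosome ends were taken as the 10 outermost genes on each arm and centromere sides as the 5 nearest genes on each side, in place of the distances planned before the data were examined. An intergenic feature is written with the genes on either side, as in EMP46-GAL2.

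The rule for named features, also fixed before the data were examined, took the 10 largest called differences per direction and contrast whose arrays did not overlap, the 15 highest bound features with all 3 arrays above 0, 1 feature per run, and for each gene of the Gal4 target and hotspot lists and for SPO11, ADH1 and GAL4 the feature with the highest mean over the DSB arrays. Other features that are named were chosen after their values were seen. These are the highest enriched features of each DSB map, the bound and broken features beside a named one, and the features weighed among the other observations.

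Alternatives tried were values without further centring, scale and quantile normalization, array weights, the replicate number as a block, features with values on every array, fits on the 2 groups compared or on a strain's own arrays, other thresholds, other position classes, members in open reading frames or intergenic regions only, and leaving out each array in turn. Where an alternative left 1 array in a group, that array was assumed to vary like those of the other groups. The procedure was tested on simulated data with normal noise of each array's residual spread. Of 100 features changed by a log2 of 1, it recovered 58 for Gal4BD-Spo11 against Spo11, 53 against pADH1-Spo11, 64 for pADH1-Spo11 against Spo11 and 35 for Gal4BD-alone against Spo11, and 99 to 100 at a log2 of 2. It called 15, 0, 25 and 2 unchanged features in these contrasts, in 1 simulation each. With scale normalization it called 155, 3, 53 and 30 unchanged features, and scale normalization stayed an alternative, as fixed before the data were examined. All 200 simulated bound features, changed by a log2 of 1.5, were recovered. Smaller changes, nearer the minimum mean log2 of 1 for a bound feature, were not simulated, so recovery there is not known. Among 100 random lists, 5 passed an unadjusted p of 0.05.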

Results

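Meiotic recombination in budding yeast starts with DNA double-strand breaks (DSBs) made by Spo11. The arrays mapped where a fusion of the Gal4 DNA-binding domain to Spo11 (Gal4BD-Spo11) bound DNA and where breaks formed in its presence. Gal4 is the activator of the galactose genes and binds sites upstream of them. Binding was measured on 3 arrays from crosslinked cells at 0 h after the induction of meiosis. Breaks were measured at 6 h without crosslinking, as DNA that came down with the Myc-tagged protein. The DSB arrays covered Spo11 (n = 3), pADH1-Spo11 (n = 3), in which the label names the ADH1 promoter, Gal4BD-Spo11 (n = 3) and a strain with Spo11 beside an unfused Gal4 domain (Gal4BD-alone, n = 2). The description field of the pADH1-Spo11 and Gal4BD-alone arrays names maps of binding sites instead. Their titles, protocol and time point name DSB maps and were followed. Each array gave values for 11437 to 12108 of 13009 features. All levels are log2 ratios of ChIP over input relative to the array median, with base 2 assumed and base e not excluded. The SD over features was 1.11 on Spo11 replicate 1, 0.49 on replicate 2 and 0.37 on replicate 3. It was 0.30, 0.24 and 0.31 on Gal4BD-Spo11 DSB replicates 1, 2 and 3. Spearman correlations across features, which are not independent replicates, were 0.42 to 0.51 between Spo11 arrays, 0.58 to 0.70 between pADH1-Spo11 arrays, 0.23 to 0.44 between Gal4BD-Spo11 DSB arrays, 0.41 between the Gal4BD-alone arrays and 0.42 to 0.70 between binding arrays.

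The binding arrays asked where the fusion sat before breaks formed. The highest signal lay in the region between GAL10 and GAL1, which encode enzymes of galactose use, on chromosome II (GAL10-GAL1, 2.65 ± 0.27, SD, n = 3, or 6.27-fold over the median feature). It was followed by TRP1-GAL3 on chromosome IV, upstream of the galactose sensor GAL3 (2.36 ± 0.27), EMP46-GAL2 on chromosome XII, upstream of the galactose permease GAL2 (2.22 ± 0.14), and GAL7, another enzyme of the pathway (2.19 ± 0.48). SUR7 (1.88 ± 0.30) and the neighbouring GAL80, the repressor of Gal4 (1.80 ± 0.38), were bound, as was MTH1-RNH202 (1.83 ± 0.45), upstream of MTH1, a regulator of glucose transporter genes. Away from the Gal4 target list, the fusion was bound at MLF3-MSK1 (1.40 ± 0.29), RUP1-SFL1 (1.24 ± 0.22) and SDD1-HAT2 (1.20 ± 0.39).

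In all, limma called 30 of 12092 features bound, in 19 runs, 15 of them intergenic and 14 in open reading frames. Of the 22 measured features of the Gal4 target list, 11 were bound (50%, against 0.157% of other features, Fisher's exact test, BH-adjusted p = 1.3e-23). They belonged to 7 of the 12 genes, GAL1, GAL2, GAL3, GAL7, GAL10, GAL80 and MTH1. The other 5 had a mean log2 under 1. These were RIO1-GCY1 (0.86 ± 0.33), RPL1B-PCL10 (0.91 ± 0.17), GAL1-FUR4 (0.70 ± 0.28), LAP3 (0.51 ± 0.33) and PGM2 (0.18 ± 0.17), for GCY1, PCL10, FUR4, LAP3 and PGM2. The remaining named bound features were YCL076W (1.17 ± 0.36), PSY2-NNR1 (1.17 ± 0.32), TAZ1 (1.17 ± 0.38), TMA7 (1.10 ± 0.24), FAA1-HSH49 (1.10 ± 0.26), an intergenic feature labelled for a leucine tRNA (1.10 ± 0.24) and one labelled for an omega element (1.05 ± 0.25). The count rose to 182 at a mean log2 of at least 0.5. SDD1-HAT2 fell below a mean log2 of 1 without binding replicate 3 (0.99), TAZ1 and TMA7 without replicate 1 (0.96 and 0.97), and the omega feature without replicate 2 (0.95).

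**Figure D1:**
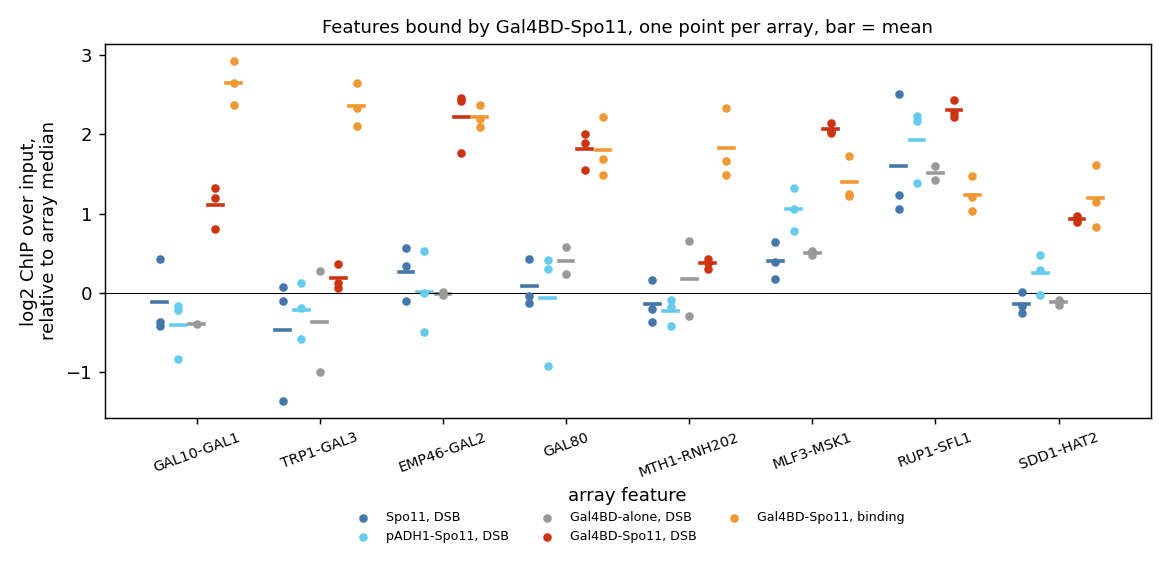
Log2 ChIP over input, relative to the array median, at 8 features bound by Gal4BD-Spo11, with 1 point per array and bars for group means. At EMP46-GAL2 the Gal4BD-Spo11 DSB mean was 2.21 and at TRP1-GAL3 it was 0.18, with binding means of 2.22 and 2.36.

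The DSB arrays of the Gal4BD-Spo11 strain asked whether bound sites were also broken. The GAL2 upstream region carried a high break signal (EMP46-GAL2, 2.21 ± 0.39, SD, n = 3), as did GAL80 (1.81 ± 0.23) with its neighbours SUR7 (1.47 ± 0.38) and SUR7-GAL80 (1.21 ± 0.09). Breaks were also called at the bound features MLF3-MSK1 (2.07 ± 0.07), MLF3 (1.54 ± 0.40) and RUP1-SFL1 (2.30 ± 0.11). These 7 features, in 4 runs, made up the overlap of the maps. With Spo11 the levels were 0.27 ± 0.34 at EMP46-GAL2, 0.09 ± 0.30 at GAL80, 0.40 ± 0.23 at MLF3-MSK1 and 1.60 ± 0.79 at RUP1-SFL1, of which the last was also called broken with Spo11. With pADH1-Spo11 they were 0.01 ± 0.51, -0.07 ± 0.74, 1.06 ± 0.27 and 1.93 ± 0.47, and both MLF3-MSK1 (adjusted p = 0.00126) and RUP1-SFL1 were called broken there. SUR7 stood at 0.98 ± 0.60 with Spo11 (adjusted p = 0.0158) and 0.83 ± 0.41 with pADH1-Spo11 (adjusted p = 0.0402), both under the minimum mean of 1. TRP1-GAL3 upstream of GAL3 was bound at 2.36 and had a break level of 0.18 ± 0.16, and MTH1-RNH202 was bound at 1.83 and had 0.37 ± 0.06. GAL7 had a break level of 1.23 ± 0.27, with 0.94, 1.24 and 1.49 on the 3 arrays, and did not pass the test (adjusted p = 0.41). That test used the spread shared by the 4 strains, and at GAL7 the Spo11 arrays ranged from -2.32 to -0.22. GAL10-GAL1 stood at 1.11 ± 0.27 (n = 3), against -0.12 ± 0.47 with Spo11 and -0.40 ± 0.37 with pADH1-Spo11. It was outside the fit because 1 Gal4BD-alone array lacked it.

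Of 27 bound features in both fits, 7 were broken with Gal4BD-Spo11 (25.9%, exact 95% interval 11.1 to 46.3), against 31 of 11253 unbound features (0.275%). The odds ratio was 126 (Fisher's exact test, two-sided, p = 2.3e-12, BH-adjusted p = 7.0e-12). The same bound features were broken at 2 of 27 with Spo11 (7.41%, against 5.73% of unbound features, exact p = 0.666). With pADH1-Spo11 they were broken at 3 of 27 (11.1%, against 4.29%, exact p = 0.108). A test of the difference between strains was not run. The bound features were chosen on this series, so this count is not independent of it. None of the bound features in both fits lay beside a centromere, 1 lay near a chromosome end and was not broken, and the other 26 held all 7 broken ones (Fisher's exact test by position, p = 1, where the smallest p that 1 such feature could give was 0.259, so position was not decided). Without Gal4BD-Spo11 DSB replicate 2 or replicate 3 the share was 3.70% (Fisher's exact p = 0.00239 each), without binding replicate 3 it was 17.6%, with breaks called as higher than pADH1-Spo11 3.70%, and with scale normalization 44.4%. Where the share was 3.70%, only 1 feature was called broken, so the test rested on that feature.

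Limma called 38 features broken in the Gal4BD-Spo11 strain, in 24 runs, 22 of them open reading frames and 16 intergenic. The highest were MRK1-MDH3 (2.34 ± 0.17), SRX1, a sulfiredoxin gene (2.32 ± 0.16), RUP1-SFL1 and EMP46-GAL2, followed by the uncharacterised YGR176W (2.12 ± 0.15). These were singled out after their values were seen. Of the 38, 22 were also broken with Spo11 and 24 with pADH1-Spo11, where 2.18 and 1.63 would follow from independence (Fisher's exact test, BH-adjusted p = 1.0e-17 and 2.6e-23). Of the Gal4 target list, features of GAL2, GAL80 and GCY1 were broken (4 of 20 features). Features of GCY1 and PGM2 were broken with Spo11 and with pADH1-Spo11 (2 of 20 each). At RIO1-GCY1 the levels were 1.21 ± 0.12 with Gal4BD-Spo11, 0.58 ± 0.62 with Spo11 and 1.07 ± 0.37 with pADH1-Spo11, where it was called broken. GCY1 itself was called with Spo11 (1.04 ± 0.68), and PGM2 stood at 0.89 ± 0.38, 1.47 ± 1.03 and 1.05 ± 0.41, called in the last 2. The count was 18 without either Gal4BD-alone array, 13 without Gal4BD-Spo11 replicate 1 and 1 without its replicate 2 or 3. It was 25, 21 and 19 without pADH1-Spo11 replicates 1, 2 and 3, 63 without Spo11 replicate 1, 277 with scale normalization and 75 in a fit on the strain's own arrays.

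The contrast of Gal4BD-Spo11 with pADH1-Spo11 asked how the breaks of the fusion differed from those of unfused Spo11 in the strain named for the ADH1 promoter. The GAL2 upstream region rose from 0.01 ± 0.51 to 2.21 ± 0.39 (n = 3 each), a log2 difference of 2.20 ± 0.29 (SE), or 4.60-fold (adjusted p = 0.0304). It was the 1 feature called higher. The 6 features called lower were all called broken in the pADH1-Spo11 strain. These were YFL032W, which overlaps HAC1 (difference -1.95 ± 0.28, adjusted p = 0.0386), VMA4, a subunit of the vacuolar proton pump (-1.84 ± 0.25, 0.0304), the neighbouring YOR331C (-1.84 ± 0.25, 0.0304), named after its values were seen, UGX2 (-1.63 ± 0.23, 0.0407), YDL144C (-1.62 ± 0.21, 0.0304) and YGL138C-SEC27 (-1.54 ± 0.19, 0.0304). VMA4, for example, stood at 2.15 ± 0.40 with pADH1-Spo11 and 0.31 ± 0.32 with Gal4BD-Spo11.

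The Gal4 target list rose as a group in this contrast. Its 20 measured features had a median difference of 0.56, with 16 above 0 and 4 below. 1 was called over all features and 8 adjusted over the list alone, all higher. Camera gave an adjusted p of 4.7e-09, and adjusted p = 0.015 with an estimated correlation. GAL80 differed by 1.88 ± 0.33 (adjusted p = 0.0824) and GAL7 by 1.97 ± 0.49 (0.179), while TRP1-GAL3 differed by 0.40 ± 0.40 (0.79). GAL10-GAL1 differed by 1.51 ± 0.28 (adjusted p = 0.107) when features of the 2 groups alone were required, a setting added after the data were seen. The list of bound features, chosen on this series and so not independent evidence, was higher at 25 of 27 features (median 0.68), with 1 called and 13 adjusted over the list alone. Its adjusted p was 3.5e-12, and adjusted p = 0.024 with an estimated correlation. The 37 hotspot features had a median difference of -0.47, with 29 lower. None was called and 7 were lower adjusted over the list alone (camera adjusted p = 2.3e-07, adjusted p = 0.18 with an estimated correlation).

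In all, 7 of 11298 features were called, 1 higher and 6 lower, and 1179 had an unadjusted p under 0.05. The count was 0 without any 1 of the Gal4BD-Spo11 arrays, either Gal4BD-alone array or pADH1-Spo11 replicate 2 or 3, it was 13 without pADH1-Spo11 replicate 1 and 547 without Spo11 replicate 1. It was 0 with the replicate number as a block, 265 (53 higher, 212 lower) with scale normalization, 200 (56 higher, 144 lower) with quantile normalization, 757 with array weights and 594 in a fit on the 2 groups. Without pADH1-Spo11 replicate 1, EMP46-GAL2 had an adjusted p of 0.0505. YFL032W lost its call with scale normalization (0.0937) and with quantile normalization (0.0609).

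The contrast of Gal4BD-Spo11 with Spo11 asked how the break map of the fusion differed from that of native Spo11. EMP46-GAL2 upstream of GAL2 rose from 0.27 ± 0.34 to 2.21 ± 0.39 (difference 1.95 ± 0.29, 3.85-fold, adjusted p = 0.0377). MLF3-MSK1 rose from 0.40 ± 0.23 to 2.07 ± 0.07 (1.66 ± 0.20, 3.17-fold, adjusted p = 0.0113). Its difference from pADH1-Spo11 was 1.01 ± 0.20 (adjusted p = 0.105). Features lower with the fusion included known hotspots. CUE1, which anchors a ubiquitin-conjugating enzyme at the endoplasmic reticulum, differed by -2.44 ± 0.37 (adjusted p = 0.0377). CCT6, a chaperonin subunit in a known hotspot, fell by 2.38 ± 0.33 (0.0225), and HAC1, the transcription factor of the unfolded protein response, fell by 2.09 ± 0.26 (0.0113). BUD23, a ribosomal RNA methyltransferase gene in a known hotspot of chromosome III, stood at 3.35 ± 0.37 with Spo11 and 1.38 ± 0.24 with Gal4BD-Spo11 (difference -1.97 ± 0.26, adjusted p = 0.0188). The other named features called lower were GNA1, AGP1, an amino acid permease gene, PPZ2, YML083C, YAP1801 and RNR2, a subunit of ribonucleotide reductase, with differences from -2.29 to -1.56. None of the features named here as lower was called lower against pADH1-Spo11. AGP1, GNA1 and PPZ2 stood at -0.06, -0.05 and 0.49 with pADH1-Spo11 (adjusted p of the fusion against it 0.73, 0.72 and 0.69). Their low levels were thus not shown to be particular to the fusion. CCT6 and HAC1 stood at 1.94 and 1.59 with pADH1-Spo11, and the fusion differed from it by -1.51 (0.138) and -1.61 (0.0606).

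The Gal4 target list rose in this contrast too. Of its 20 features 17 were higher (median 0.62), with 1 called and 6 higher adjusted over the list alone (camera adjusted p = 4.9e-06, adjusted p = 0.044 with an estimated correlation). GAL80 differed by 1.72 ± 0.33 (adjusted p = 0.0586) and GAL7 by 2.23 ± 0.49 (0.0703). The hotspot list had 26 of 37 features lower (median -0.47), with CCT6 and BUD23 called. Adjusted over the list alone, 13 were lower and 1 higher. Its camera adjusted p was 1.1e-04, with adjusted p = 0.31 with an estimated correlation and 0.114 with scale normalization (median -0.22). The median was -0.21 without Spo11 replicate 1 (adjusted p = 0.00112) and -0.77 without Spo11 replicate 3. Examples below the threshold over all features were CYS3 (-1.87 ± 0.39, adjusted p = 0.0703), a gene of cysteine synthesis, and the transcription factor gene GAT1 (-1.97 ± 0.36, 0.058). The bound features, chosen on this series and so not independent evidence, were higher at 20 of 27 (median 0.70), with 2 called and 11 adjusted over the list alone (adjusted p = 1.8e-05, adjusted p = 0.13 with an estimated correlation).

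In all, 16 features were called, 2 higher and 14 lower, and 2186 had an unadjusted p under 0.05. The count was 0 without any 1 of the Gal4BD-Spo11 arrays, 5 without either Gal4BD-alone array, 8 without pADH1-Spo11 replicate 3 and 6 without Spo11 replicate 2. It was 82 without Spo11 replicate 1 and 786 without Spo11 replicate 3. It was 0 with the replicate number as a block, 438 (176 higher, 262 lower) with scale normalization, 521 (217 higher, 304 lower) with quantile normalization, 1433 with array weights and 0 in a fit on the 2 groups. EMP46-GAL2 also lost its call without pADH1-Spo11 replicate 1 (adjusted p = 0.0523), and BUD23 with scale normalization (-0.57, adjusted p = 0.58) and quantile normalization (0.0854).

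**Figure D2:**
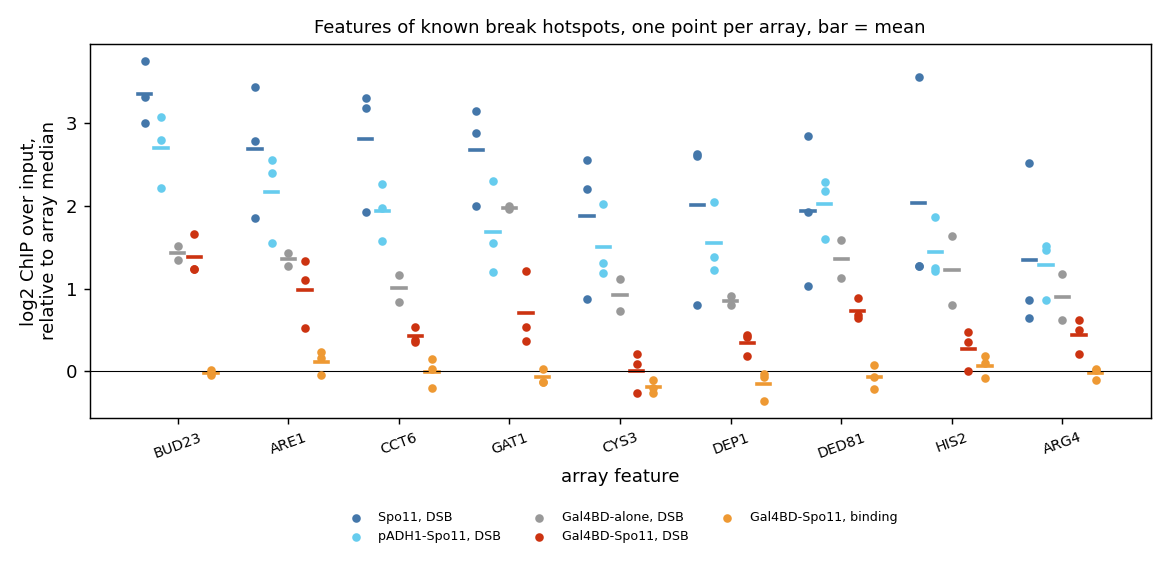
Log2 ChIP over input, relative to the array median, at 9 features of known DSB hotspots, with 1 point per array and bars for group means. At BUD23 the mean was 3.35 with Spo11, 2.70 with pADH1-Spo11, 1.43 with Gal4BD-alone, 1.38 with Gal4BD-Spo11 and -0.02 on the binding arrays.

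The Spo11 and pADH1-Spo11 maps showed where unfused Spo11 broke DNA and served as promoter control. BUD23 had the highest Spo11 level (3.35 ± 0.37, n = 3), and YGR176W the highest pADH1-Spo11 level (3.17 ± 0.52). Among the highest in both were YMR265C (3.12 ± 0.69 and 2.56 ± 0.74) and AAC1, a mitochondrial ADP/ATP carrier gene (2.70 ± 1.04 and 2.50 ± 0.53), chosen after their values were seen. Of the 21 genes of the hotspot list, 9 were broken in both strains. These were ARE1, ARG4, BUD23, CCT6, CYS3, DED81, DEP1, GAT1 and HIS2. ARG4, an arginine synthesis gene, stood at 1.34 ± 1.02 and 1.28 ± 0.36. The 12 others included HIS4-BIK1 (0.41 ± 0.27, n = 2, and 0.45 ± 0.12), THR4 (0.56 ± 0.53 and 0.61 ± 0.25), PES4 (0.95 ± 0.56 and 0.45 ± 0.39) and CHA1-VAC17 (-0.37 ± 0.32 and -0.16 ± 0.16). At single features, 37.8% of the list was broken with Spo11 against 5.62% of other features (Fisher's exact test, BH-adjusted p = 4.4e-08), and 40.5% against 4.18% with pADH1-Spo11 (1.4e-10).

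Spo11 breaks were called at 647 features in 326 runs and pADH1-Spo11 breaks at 486 features in 275 runs. They shared 309, where 27.8 would follow from independence (Fisher's exact test, BH-adjusted p = 7.5e-286). Limma called 0 features different between the strains, while 1406 had an unadjusted p under 0.05. Among the named hotspot features the largest shift up from Spo11 to pADH1-Spo11 was at CTR86 (-0.45 ± 0.39 and 0.59 ± 0.38, adjusted p = 0.23) and the largest down at GAT1 (2.68 ± 0.60 and 1.68 ± 0.57, adjusted p = 0.33). No list passed, with the lowest adjusted p at ribosomal protein genes and at Ty and long terminal repeat features (0.13 each). Some lists passed under alternatives. With members in open reading frames alone, ribosomal protein genes (1.5e-04) and glycolytic genes (0.035) passed, both higher. Ty and repeat features passed without Spo11 replicate 2 (higher, 0.0198), and bound features without Spo11 replicate 1 (lower, 0.0182). With array weights 168 features were called, and without Spo11 replicate 3, 1 was. The Spo11 count was 283 without Spo11 replicate 1, 1046 without replicate 3, 351 with scale normalization and 0 in a fit on its own arrays (685 with an unadjusted p under 0.05 and a mean log2 of at least 1 in the fit with all strains). The pADH1-Spo11 count was 132 without its replicate 2 and 175 without its replicate 3.

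The Gal4BD-alone strain served to ask whether the break map differed when an unfused domain was present beside Spo11. None of the 21 genes of the hotspot list was called broken there, and the levels of their named features ranged from -0.69 ± 0.13 (n = 2) at CHA1-VAC17 to 1.98 ± 0.03 at GAT1, with 0.15 ± 0.35 at HIS4-BIK1 and 1.43 ± 0.12 at BUD23. Of the 20 named hotspot features in the fit, 16 were lower than with Spo11. Over the whole hotspot list 25 of 37 features were lower (median -0.26, camera adjusted p = 0.12). The list's array medians were 0.61 and 0.41, within the range of the Spo11 arrays (1.19, 0.29 and 0.25). A loss of hotspot signal in this strain was thus not shown. The Gal4 target list had array medians of 0.06 and 0.04. Among its features with values on both arrays, the means ranged from -0.89 ± 0.26 at GAL3 and -0.83 ± 0.12 at GAL1 to 0.64 ± 0.04 at PGM2, with -0.01 ± 0.03 at EMP46-GAL2, 0.41 ± 0.24 at GAL80 and -0.36 ± 0.91 at TRP1-GAL3. Limma called 0 features broken with 2 arrays, while 174 had an unadjusted p under 0.05 and a mean log2 of at least 1. The number called was 131 with scale normalization, 169 without Spo11 replicate 1, 25 without Spo11 replicate 3, 9 without Gal4BD-alone replicate 2 and 2 without pADH1-Spo11 replicate 3. Against Spo11, 0 features were called, with 1323 at an unadjusted p under 0.05, 5 (all higher) with quantile normalization, 8 (all lower) without Spo11 replicate 3 and 5 (all higher) without Gal4BD-alone replicate 2. No list passed (lowest adjusted p = 0.12). The Gal4 target list had a median difference of -0.08 (adjusted p = 0.99). Without Spo11 replicate 3 the hotspots (lower) and the centromere sides (higher) passed, at 0.00931 each, and without Gal4BD-alone replicate 2 the Ty and repeat features did (higher, 0.035). With members in open reading frames alone, ribosomal protein genes (0.00297) and glycolytic genes (0.0173) passed, both higher, as did a narrower class of centromere sides (higher, 0.0429).

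The maps also differed by chromosome region. With Spo11, 0.748% of features at chromosome ends were broken against 5.91% elsewhere (Fisher's exact test, BH-adjusted p = 1.2e-06), and 0.69% beside centromeres against 5.86% (2.5e-05). With pADH1-Spo11 the shares were 0.249% against 4.45% (3.7e-06) and 0 of 290 against 4.42% (2.4e-05). Chromosomes I, III and VI had 10.04% of features broken with Spo11 against 5.45% elsewhere (1.3e-05), and 5.39% against 4.23% with pADH1-Spo11 (0.255). Intergenic features were broken less often than others with Spo11 (3.51% against 7.86%, 1.4e-22) and with pADH1-Spo11 (3.68% against 4.90%, 0.00476). In the Gal4BD-Spo11 strain, the shares were 0.499% against 0.33% at chromosome ends (0.979) and 0 of 290 against 0.345% beside centromeres (1). That strain had only 38 broken features in all, too few for these tests to show a depletion like that with Spo11.

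Against Spo11, the fusion's levels were higher at chromosome ends (263 of 401 features, median 0.19, camera adjusted p = 5.2e-04), where adjusted p = 0.31 with an estimated correlation and 0.0647 with scale normalization (median 0.09). Without Spo11 replicate 1 the median was 0.10 (adjusted p = 0.0093). They were higher beside centromeres (212 of 290, median 0.22, adjusted p = 1.1e-04), where adjusted p = 0.30 with an estimated correlation. The median there was 0.11 without Spo11 replicate 1 (adjusted p = 0.00246) and 0.10 with scale normalization (0.0369). They were lower on chromosomes I, III and VI (394 of 687, median -0.10, adjusted p = 0.028), where adjusted p = 0.30 with an estimated correlation and 0.0629 without Spo11 replicate 2, and the median was -0.16 without Spo11 replicate 3. Against pADH1-Spo11, chromosome ends were higher at 292 of 401 features (median 0.21, adjusted p = 5.5e-07, adjusted p = 0.15 with an estimated correlation, median 0.13 without pADH1-Spo11 replicate 2) and centromere sides at 210 of 290 (median 0.16, adjusted p = 1.4e-04, adjusted p = 0.20 with an estimated correlation). The short chromosomes did not pass there (-0.06, adjusted p = 0.066), but did without Spo11 replicate 2 (0.049). The fusion's own median level at chromosome ends was -0.03, against -0.21 with Spo11 and -0.23 with pADH1-Spo11. Beside centromeres it was -0.06, against -0.27 and -0.21. Higher levels in both classes thus lay nearer the array median, not above it. The SD over features was also smaller on the Gal4BD-Spo11 DSB arrays (0.24 to 0.31) than with Spo11 (0.37 to 1.11) or pADH1-Spo11 (0.34 to 0.62). Scale normalization, which evens out this spread, left smaller differences from Spo11 (medians 0.09 and 0.10). Less depletion in these regions was therefore not told apart from a narrower spread over all features. None of these features at chromosome ends or beside centromeres was called, over all features or adjusted over the list alone. On the short chromosomes 5 were called lower against Spo11 and 1 against pADH1-Spo11, and 35 lower and 2 higher, and 6 lower, adjusted over the list alone.

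**Figure D3:**
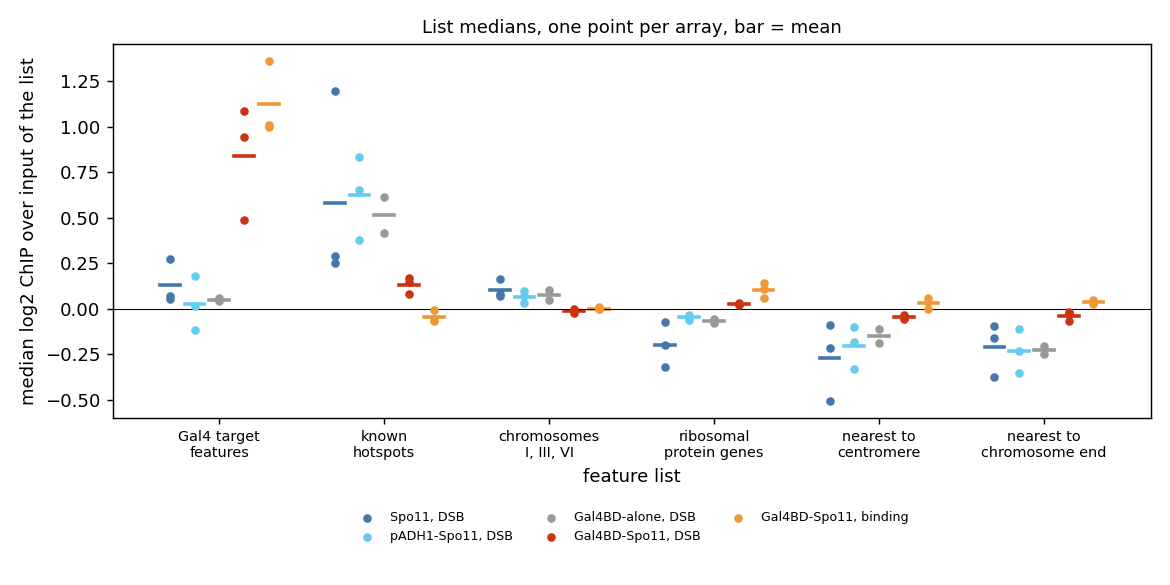
Median log2 ChIP over input of 6 feature lists, with 1 point per array and bars for the mean of the arrays of each group. The Gal4 target list averaged 0.84 on the Gal4BD-Spo11 DSB arrays and 0.13 on the Spo11 arrays, and the hotspot list 0.13 and 0.58. Without Spo11 replicate 1 the Spo11 averages were 0.06 and 0.27.

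Against Spo11, ribosomal protein genes were higher at 136 of 214 features (median 0.16, adjusted p = 0.0012, adjusted p = 0.095 with an estimated correlation), with none called over all features or adjusted over the list alone. With upstream intergenic members alone the adjusted p was 0.249. Ty elements and long terminal repeats were higher at 69 of 107 (median 0.09, adjusted p = 0.03, adjusted p = 0.49 with an estimated correlation), with none called either way. That call was lost without Gal4BD-Spo11 replicate 1 (0.0835), Spo11 replicate 1 (0.0881) or Spo11 replicate 3 (0.104). Early meiotic genes (median 0.14, 1 lower adjusted over the list alone) had an adjusted p of 0.082, and 0.0229 without Gal4BD-Spo11 replicate 1. Glycolytic genes (-0.01, 0.72), loci of constructs and markers (0.20, 0.66), seripauperin and COS genes (0.10, 0.36), tRNA genes (0.03, 0.82) and intergenic features (0.84) did not pass.

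Against pADH1-Spo11, 3 small lists lay just past the threshold. Glycolytic genes had 12 of 16 features lower (median -0.26, or -0.13 without pADH1-Spo11 replicate 2, adjusted p = 0.048, adjusted p = 0.15 with an estimated correlation, 2 lower adjusted over the list alone). Loci of constructs and markers had 7 of 10 higher (0.32, adjusted p = 0.035, adjusted p = 0.20 with an estimated correlation, none adjusted over the list alone). Seripauperin and COS genes had 12 of 14 higher (0.20, adjusted p = 0.048, adjusted p = 0.15 with an estimated correlation, none adjusted over the list alone). The loci lost the call without Gal4BD-Spo11 replicate 1 (0.139), pADH1-Spo11 replicate 1 (0.072) or Spo11 replicate 1 (0.0521). The glycolytic genes lost it without Gal4BD-alone replicate 2 (0.0563), Gal4BD-Spo11 replicate 1 or 3 (0.0859 and 0.0761), pADH1-Spo11 replicate 1 or 2 (0.0979 and 0.0615) or Spo11 replicate 1 or 3 (0.0521 and 0.0553). The seripauperin and COS genes lost it without Gal4BD-alone replicate 2 (0.0563), Gal4BD-Spo11 replicate 2 or 3 (0.0724 and 0.124), pADH1-Spo11 replicate 1 or 2 (0.0534 and 0.157) or Spo11 replicate 1 or 3 (0.0521 and 0.0553), with scale normalization (0.242) and with the replicate block (0.0572). With members in open reading frames or upstream regions alone, the adjusted p was 0.213 and 0.134 for glycolytic genes, 0.0871 and 0.197 for the loci, and 0.437 and 0.0848 for seripauperin and COS genes. Ribosomal protein genes (0.05, adjusted p = 0.077) passed without pADH1-Spo11 replicate 3 (0.0271), and Ty and repeat features (-0.02, 0.84) passed with scale normalization (0.00472, higher). Early meiotic genes (-0.03, 0.78), tRNA genes (0.02, 0.78) and intergenic features (0.84) did not pass. The direction of the camera test, which is relative to all other features, was opposite to the sign of the median for early meiotic genes, Ty and repeat features and intergenic features in this contrast. The same held for intergenic features against Spo11, for hotspots and tRNA genes between pADH1-Spo11 and Spo11, and for intergenic and bound features between Gal4BD-alone and Spo11. For chromosome ends between pADH1-Spo11 and Spo11 the mean and the median differed in sign. None of these passed.

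At the loci that carry parts of the constructs, the region upstream of SPO11 (SPO11-AIM17) stood at 1.11 ± 0.45 on the Gal4BD-Spo11 DSB arrays and 0.02 ± 0.10 on the Spo11 arrays. The difference was 1.09 ± 0.26 (adjusted p = 0.0941) with features of the 2 groups alone required. ADH1-YOL085C stood at 0.46 ± 0.52 and 0.75 ± 0.50 (difference -0.29 ± 0.31, adjusted p = 0.603). GAL4 stood at 0.71 ± 1.61 on the Gal4BD-Spo11 DSB arrays, with 2.57 on replicate 1, -0.14 on replicate 2 and -0.28 on replicate 3 (difference from Spo11 0.74 ± 0.58, adjusted p = 0.477).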

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

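No named feature past its threshold and none of the 16 list tests past the threshold changed direction under the alternatives tried. For the named features this was partly fixed by their choice. Their arrays did not overlap between the groups, or all 3 binding arrays were above 0, so leaving out an array could not reverse them. Of the 40 list tests that did not pass, 21 had the opposite direction under at least 1 alternative, never past the threshold. The features called for Gal4BD-alone against Spo11 were all higher with quantile normalization or without Gal4BD-alone replicate 2, and all lower without Spo11 replicate 3. The fits on a strain's own arrays, the requirement of values in the 2 compared groups only, and the reruns of the bound and broken comparison with scale normalization, with own-array fits and without single arrays were added after the data were seen. The others were planned. The number of arrays limits precision, and signal over background was not analysed here.

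For Gal4BD-Spo11 against Spo11 (16 called), scale normalization gave 438 (176 higher, 262 lower), quantile normalization 521, array weights 1433, and the replicate block, a fit on the 2 groups and an adjusted p under 0.01 gave 0 each. Leaving out 1 array gave 0 to 786. For Gal4BD-Spo11 against pADH1-Spo11 (7 called), the counts were 265 (53 higher, 212 lower), 200, 757, 0 with the block, 594 with the 2 groups and 0 under 0.01, and 0 to 547 without 1 array. For pADH1-Spo11 against Spo11 (0 called), array weights gave 168 and leaving out 1 array 0 to 1. For Gal4BD-alone against Spo11 (0 called), quantile normalization gave 5 and leaving out 1 array 0 to 8. Smaller counts without 1 array follow in part from fewer arrays. Spo11 arrays enter the contrast of Gal4BD-Spo11 with pADH1-Spo11 only through the shared spread and the choice of features. Its 547 calls came without Spo11 replicate 1, the array with the largest SD over features (1.11). The count of 7 thus depended on arrays of a strain outside the contrast. For the other changes the cause was not tested.

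Spo11 breaks (647) numbered 351 with scale normalization, 0 on own arrays, 389 at an adjusted p under 0.01, 1334 at a mean log2 of at least 0.5, and 283 to 1046 without 1 array. pADH1-Spo11 breaks (486) numbered 319, 997 and 132 to 597 under the last 3 of these. Gal4BD-alone breaks (0) numbered 131 with scale normalization and 0 to 169 without 1 array. Gal4BD-Spo11 breaks (38) numbered 277 with scale normalization, 75 on own arrays, 14 at an adjusted p under 0.01 and 1 to 63 without 1 array. Binding (30) gave 182 features at a mean log2 of at least 0.5 and 25 to 39 without 1 array. The share of bound features that were broken (25.9%) ranged from 3.70% to 44.4% and kept its side of the test under all 13 alternatives. In the settings with 3.70%, only 1 feature was called broken and it was bound, so the test rested on that feature. Of 56 list tests, 16 passed, 3 with an estimated correlation and 13 to 17 without 1 array. The cause was not tested, apart from thresholds, which act by construction.

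Among named features, 272 values under alternatives kept their call and 172 kept the direction but lost the call. For lists these numbers were 275 and 45. Of 20 overlaps of enriched sets under other thresholds, 6 stayed within 1.5 times of the reported count and 14 did not.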

Other observations

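The tests of the GAL4 signal on 1 array, of the 2 runs on the Gal4BD-alone arrays and of the bound features away from Gal4 targets were chosen after the results were seen, and the criteria for GAL4 and for cloned DNA and the division of the bound features by break level after their values were. Those of promoters, of nearby breaks and of other splits of the arrays were written before.

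Intergenic regions with a promoter carried more break signal than regions between convergent genes. With Spo11 the mean log2 was 0.149 over 1484 divergent regions, 0.0463 over 2649 tandem regions and -0.0405 over 1378 convergent regions. Divergent and tandem regions together exceeded convergent ones by 0.124, and did so on 3 of 3 arrays (0.0432 to 0.289; permutation p = 1e-05, the smallest that the permutations can give). The excess was 0.179 with pADH1-Spo11 and 0.0438 with Gal4BD-Spo11, on 3 of 3 arrays each with the same p. It was 0.0153 with Gal4BD-alone (1 of 2 arrays, permutation p = 0.175) and 0.0174 on the binding arrays (2 of 3 arrays, permutation p = 0.00096). Among intergenic regions Spo11 may thus cut more near promoters, but intergenic features as a whole were broken less often than others with Spo11 (3.51% against 7.86%), and the binding arrays at 0 h, which did not map breaks, had an excess too. The permutations treated regions as independent, and differences between strains were not tested.

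Natural break features near the 7 bound and broken features could lose breaks to them. The 6 natural break features within 15 features of these sites had a median difference from pADH1-Spo11 of -0.38, against -0.73 for 640 others. The near ones were higher by 0.358 (permutation p = 0.109), the opposite side from such a loss. With 6 near features and this p, the difference was within chance, so the question stays open, although the written criterion against a loss was a median that was not lower.

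GAL4, TRP1 and the neighbouring YDR008C were raised on replicate 1 of the 3 Gal4BD-Spo11 DSB arrays, by 2.78, 1.60 and 1.52 over the other 2 arrays. DNA of the fusion construct in that sample would also raise SPO11, whose excess was 17.4% of that of GAL4, but the region upstream of ADH1, which such a construct could hold, had 31.8%, so this stays open. Binding or breakage at the chromosomal GAL4 locus would spread to its flanks, but the ratio of flank to peak at GAL4 (-0.06) lay below that of all 35 isolated peaks of the array (percentile 0, median ratio 0.29). Cloned DNA with GAL4 and TRP1 sequence but without SPO11 stays open too, since the 8 flanking features had a median excess of 12.6% of that of the 3 raised features, but SOK1-TRP1 beside TRP1 had 56.5%. No biological explanation beyond the locus itself was tested.

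On the Gal4BD-alone arrays, 2 runs of 4 and 5 features, from YDL221W past CDC13 and DTD1, and from MFT1 past PIF1 to OGG1, were raised over the Spo11 mean by a median of 3.24 on replicate 1 and 1.00 on replicate 2. One faulty array would leave replicate 2 unremarkable, but there the runs' median of 0.68 lay at percentile 99.77 of 10000 random pairs of runs, with 23 as high. The runs were first noticed in the mean of both arrays, but the 2 highest features of replicate 1 alone, DTD1 and PIF1, give the same runs. The percentile replaced 2 earlier versions whose results had been seen, the median percentile of single features (95.01, at the edge of its criterion) and a comparison of excesses over the shared Spo11 arrays. Cloned DNA in these samples stays open, since the 4 first features outside the runs had a median excess of -0.967% of that inside on replicate 2, but YDL218W had 57.1% (replicate 1, which set the edges, had 0.0393%, with 13.3% at the highest), and no biological explanation was tested.

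Away from Gal4 targets, 10 bound features were not broken, with binding means of 1.01 to 1.20 and a median break level of -0.16. Binding replicate 3 was the highest array at 15 of 15 features of the bound Gal4 target runs and at 10 of 11 unbound Gal4 target features. It was the highest at 0% of the 8 with break levels of -0.33 to -0.05, where it was the lowest, a ranking unlike that at the targets. At the other 2, SDD1-HAT2 and TPO1-ISA1 (break levels 0.93 and 0.52), it was the highest (100%), and 2 features are too few to decide. The division by break level came after the values were seen. Over the undivided 10, replicate 3 was the highest at 2, which missed the criterion against weak binding of the same kind, so such binding stays open. A property of the spots or DNA shared with other strains could raise the 10 on Spo11 arrays, where their median percentiles were 28.1, 89.2 and 82.0, between the criteria, so it stays open.

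Other splits of the 6 arrays were too few for a share under 0.05, with 10 splits per contrast. For Gal4BD-Spo11 against Spo11 the real split gave 16 called features and the highest other 0, so 1 split, the real one, had as many. For Gal4BD-Spo11 against pADH1-Spo11 these were 7 and 0, again with 1 split. For pADH1-Spo11 against Spo11 they were 0 and 1, with all 10 splits at or above the real value.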
